A study of Arabidopsis thaliana with 24 samples.

How the data were processed

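The deposited table holds 1 value per probe set and array, on the log2 scale, for 22810 probe sets and 24 Affymetrix arrays. The authors computed these values with GCRMA, per the submitters' processing notes; the version of GCRMA is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin in the one-cycle target labelling assay. No sequencing was involved. The lowest value in the table was 2.1961 log2 and 25.5% of all values lay within 0.001 log2 of it, so weakly expressed probe sets pile up at that floor. No further normalization was applied for the reported results.

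The 64 control probe sets were set aside. A probe set was tested if at least 3 of the 24 arrays, whichever they were, had a log2 value of 5 or more, which left 11926 probe sets. Gene names came from the platform annotation and from the TAIR10.1 reference annotation, which was used for names only. Of the 22746 probe sets that were not controls, 13513 were assigned to exactly 1 gene, 503 to several genes and 8730 to none in that annotation. The 13513 probe sets with 1 gene cover 13356 genes, and 13367 of them have a locus name that starts with AT. Well-known genes whose probe sets carry no name in the annotation therefore count among the probe sets tested but are not named here.

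Differences were tested with limma 3.58.1 in R 4.3.3. One linear model held a mean for each of the 8 groups of 3 arrays, and all groups shared 1 estimate of the spread, moderated across probe sets without a trend on the mean. That estimate had 16 residual degrees of freedom and 4.57 prior degrees of freedom. The contrasts were water-limited minus well-watered at each of the 4 times, the mean of these 4 contrasts, the moderated F-test of whether they differ, and the moderated F-test of the 4 times within each water regime. The tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 11926 probe sets of each contrast. An adjusted p under 0.05 was the threshold. The 6 pairwise differences between the drought effects at 2 times were adjusted in the same way, each on its own. The word rose or fell is used for changes past that threshold.

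The groups, the filter, the model, the threshold, the gene lists named next and the recomputations other than those described as added were chosen before the data were examined. For each time, the named genes are the 8 with the largest rise and the 8 with the largest fall among probe sets assigned to exactly 1 gene, past the threshold, with no overlap between the 3 and the 3 arrays. For the average over the times they are the 5 largest rises and 5 largest falls, for the difference between times the 10 smallest p, and for each time-of-day effect the 5 largest ranges between group means. Members of gene lists may also be named, and no gene named here has several probe sets in the test.

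The 23 gene lists fixed in advance held 375 members, of which 49 were named on the array and 38 were tested. They covered ABA- and dehydration-responsive genes, ABA receptors, clade A protein phosphatases 2C, ABA synthesis and breakdown, proline and raffinose-family metabolism, CBF/DREB and ZAT transcription factors, the circadian clock, photosynthesis, starch turnover, sugar starvation, expansins and xyloglucan hydrolases, aquaporins, Aux/IAA genes, jasmonate, salicylate and defence, heat shock, flavonoids and anthocyanins, glucosinolates, cell division, senescence, guard cells, roots, and flowering and bolting. Lists with at least 3 tested members were compared with all other probe sets by camera with a preset correlation between genes of 0.01, adjusted over the lists of 1 contrast, and again with an estimated correlation. A list of cytosolic ribosomal proteins was planned and not run, because the annotation gives neither products nor systematic symbols for them. A further 17 lists were built from the symbols in the annotation after it had been read and before any expression value was tested; they held 319 members, of which 171 were tested.

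The results were recomputed with no filter, a stricter filter (mean of at least 6 log2), moderation with a trend and robust estimation, centring each array on its median, quantile normalization, array quality weights, the replicate number as a block, probe sets with exactly 1 gene alone, the 6 arrays of 1 time alone, an unmoderated F-test, and leaving out each array in turn. The default method of array weights did not converge, and the gene-by-gene method was used in its place. For the drought effects, the block was a term for each pair of arrays of equal number at 1 time. For time of day it was the number itself. A fit without the 6 late-day arrays and fits with the differences between 3-prime and 5-prime control probe sets of GAPDH, actin and ubiquitin as covariates were added after the data were seen. Other splits of the arrays into groups of the same sizes were fitted in the same way.

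The test was tested on simulated data in which 200 of the 11926 probe sets were given a known change. At 4-fold it found 98.5% of them at midday, late day and midnight and 97% at pre-dawn. At 2-fold it found 68.7% at midday, 64.2% at late day, 67.2% at midnight and 71.6% at pre-dawn, and at 1.5-fold between 13.4% and 28.4%. The average over the 4 times recovered 82.1% of 1.5-fold changes, whereas the test of a difference between times recovered 29.9% of 2-fold and 81.8% of 4-fold changes. The simulated spread of a probe set was its mean over the 8 groups, so these rates do not compare the real spread of the times. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.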

Results

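Transcript levels were measured in whole rosettes of Arabidopsis thaliana Col-0 on 24 Affymetrix arrays. Plants were 32 days old and grew under a 12 h photoperiod. Well-watered plants received water throughout, and water-limited plants were watered for 28 days and then had 4 days without water. Rosettes of both regimes were sampled at midday (12 h), late day (18 h), midnight (0 h) and pre-dawn (6 h), which gives 8 groups of 3 arrays, described as biological replicates by the labels. Array medians lay between 4.66 and 4.86 log2, and the highest value was 15.17 log2. The number of arrays limits the precision of every value below. Changes are water-limited minus well-watered in log2 units, group values are means ± SD over n = 3 arrays, SE is the standard error of a change from the fit of all arrays, and adjusted p is from limma. In each gene named by the size of its change at a single time, all 3 arrays of one regime lay above all 3 of the other, a separation that chance gives in 10% of probe sets.

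The first question was which transcripts differed between the 4 times within each water regime. COR27 (AT5G42900), a cold-regulated gene linked to the clock, had means of 7.98 log2 at midday, 6.64 at late day, 2.79 at midnight and 9.4 at pre-dawn in well-watered plants. Its range of 6.62 log2 in well-watered and 6.29 in water-limited plants was far larger than the SE of its drought effect at one time, 0.4 (adjusted p = 2.24e-10 and 5.87e-10). Among probe sets assigned to exactly 1 gene, AT1G07050, which encodes a CCT-motif protein, had the widest range in well-watered plants. It went from 2.43 log2 at late day to 9.75 at pre-dawn, a range of at least 7.32 log2, against 6.94 under water limitation. The range is a lower bound, since 1 of these late-day arrays lay at the floor of the table. Among the same probe sets, AT2G41250 had the widest range in water-limited plants, 7.44 log2, with a mean of 11.63 at late day and 4.18 at pre-dawn. AT1G56300 spanned 6.56 log2 in well-watered and 6.91 in water-limited plants, AT4G16146 spanned 6.53 and 6.3, and AT1G49200 spanned 6.4 and 5.58. The clock gene GI differed between times with adjusted p = 2.11e-19 in well-watered and 9.38e-20 in water-limited plants. Of the 38 genes tested from the lists fixed in advance, 24 differed between times in well-watered and 29 in water-limited plants. They included all 7 photosynthesis genes and all 4 ABA- and dehydration-responsive genes in both regimes, and neither of the 2 cell division genes. Of 44 plastid-encoded photosynthesis genes, a list added later, 3 differed between times in well-watered and 6 in water-limited plants.

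Of 11926 probe sets tested, 5954 (49.9%) differed between times in well-watered plants and 6389 (53.6%) in water-limited plants, 2982 and 3047 of them by at least 2-fold. At an unadjusted p under 0.05 the counts were 6833 and 7172. In well-watered plants 825 of these probe sets (13.9%) were highest at midday, 2010 (33.8%) at late day, 1532 (25.7%) at midnight and 1587 (26.7%) at pre-dawn. In water-limited plants the corresponding counts were 1031, 2188, 1283 and 1887. Both regimes shared 4651 probe sets, where 3190 were expected from the sizes of the sets, and 3582 of them (77%) were highest at the same time. The expected count treats the calls as independent, while both tests used the same estimate of the spread of a probe set, which can raise the overlap.

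The next question was which transcripts differed between the water regimes at each time. At pre-dawn, 4 of the 8 genes named for a rise belong to anthocyanin synthesis and decoration. AT5MAT (AT3G29590), an anthocyanin malonyltransferase, rose from 3.43 ± 0.28 log2 in well-watered plants to 7.09 ± 0.93 in water-limited plants, a change of 3.67 (SE 0.45, 12.7-fold, adjusted p = 0.00049). DFR (AT5G42800), a dihydroflavonol reductase, rose from 8.06 ± 0.28 to 11.04 ± 1.01, a change of 2.97 (SE 0.5, 7.86-fold, adjusted p = 0.00239). UF3GT (AT5G54060), a glycosyltransferase of anthocyanins, rose by 3.00 log2 (SE 0.49, 8.02-fold, adjusted p = 0.00191). The anthocyanin glucosyltransferase gene AT4G14090 rose by 3.12 log2 (SE 0.63, 8.72-fold, adjusted p = 0.00721). DFR, UF3GT and AT4G14090 are the only tested members of the flavonoid and anthocyanin list fixed in advance, which held 15. All 3 rose at pre-dawn, and with all 3 past the threshold over all probe sets the adjustment over the list alone could not come out otherwise. Their median change was 3.00, and the list ranked above other probe sets (camera adjusted p = 4e-05; adjusted p = 0.0534 with an estimated correlation).

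**Figure D1:**
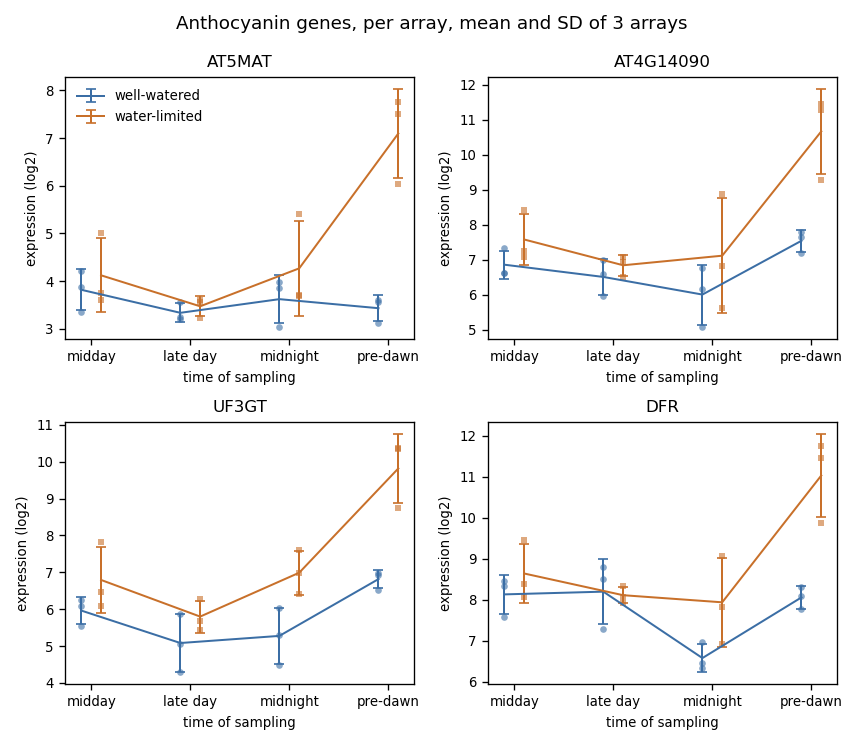
Expression (log2) of anthocyanin genes at the 4 times of day in well-watered and water-limited plants, with points for single arrays and bars for the mean and SD of 3 arrays. At pre-dawn the mean of DFR was 8.06 in well-watered and 11.04 in water-limited plants.

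Other pre-dawn rises were of different kinds. The CC-type glutaredoxin genes AT3G62960 and AT4G33040 rose by 3.03 log2 (SE 0.61, adjusted p = 0.00686) and 2.39 (SE 0.48, adjusted p = 0.00638). AT2G25625, the chloroplast vesiculation gene, which takes part in the stress-induced breakdown of chloroplasts, rose from 4.63 ± 0.29 to 7.2 ± 0.79, a change of 2.57 (adjusted p = 0.00352). The sucrose transporter gene SWEET13 (AT5G50800) rose from 6.15 ± 1.5 to 8.68 ± 0.73, a change of 2.52 (SE 0.63, adjusted p = 0.0196).

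Of the 8 genes named for a fall at pre-dawn, AT1G25550 had the largest. This gene, which encodes a repressor of nitrate-starvation genes, fell from 6.91 ± 0.37 to 4.62 ± 1.05, a change of −2.28 (SE 0.4, 4.87-fold lower, adjusted p = 0.00266). UGT76C2 (AT5G05860), a cytokinin glucosyltransferase, fell from 5.94 ± 0.1 to 4.46 ± 0.67, a change of −1.48 (SE 0.25, adjusted p = 0.00247). AT3G47800 fell at pre-dawn (−1.58, adjusted p = 0.00378) and at midnight (−1.39, adjusted p = 0.0365). MSRB6 (AT4G04840), a methionine sulfoxide reductase, changed by −1.63 (adjusted p = 0.0253) and the receptor kinase gene AT1G35710 by −1.51 (adjusted p = 0.0128). AT5G52760 changed by −1.95 (adjusted p = 0.0317), AT1G49500 by −1.86 (adjusted p = 0.0401) and AT3G06070 by −1.47 (adjusted p = 0.0155). The expansin gene EXPA8 (AT2G40610) fell by 1.41 log2 (SE 0.3, adjusted p = 0.00942), while the other 4 tested genes of expansins and xyloglucan hydrolases were not past the threshold (1 lower adjusted over the list alone; camera adjusted p = 0.183). Among the 7 photosynthesis genes, the antenna gene LHCB4.3 rose by 0.66 log2 (adjusted p = 0.0189) and LHCB4.2 fell by 0.57 (adjusted p = 0.0364), with 1 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.473. None of the 4 tested ABA- and dehydration-responsive genes, COR15A, COR15B, COR47 and LTI30, was past the threshold of limma at pre-dawn or at any other time (0 of 4, also 0 adjusted over the list alone). Their median changes were −0.57 at midday, −0.14 at late day, 0.36 at midnight and 0.04 at pre-dawn, with camera adjusted p of 0.138, 0.567, 0.206 and 0.812. That list held 30 members and only 5 were named on the array, so most of it was not tested.

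In total 864 probe sets (7.24%) differed between the regimes at pre-dawn, 489 higher and 375 lower in water-limited plants, and 341 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2895, against 596 by chance, and in 3797 probe sets (31.8%) the 3 and 3 arrays did not overlap. The count rested on single pre-dawn arrays. It was 91 without water-limited replicate 1, 114 without water-limited replicate 3, 1793 without water-limited replicate 2, 186 without well-watered replicate 1 and 245 without well-watered replicate 3. AT5MAT, UF3GT, DFR, AT2G25625, AT1G25550, AT3G47800, UGT76C2 and the flavonoid glucosyltransferase gene UGT78D2 (change 2.12, adjusted p = 0.00156) stayed past the threshold without any one array. AT3G62960, AT4G33040 and AT4G14090 were not past it without water-limited pre-dawn replicate 1 or 3, EXPA8 without these or well-watered pre-dawn replicate 1, and the remaining pre-dawn genes above without these or well-watered replicate 1 or 3 (LHCB4.2 also without well-watered replicate 2). The difference between 3-prime and 5-prime GAPDH control probe sets, a measure of RNA quality, was 1.598, 1.639 and 1.583 log2 in the water-limited pre-dawn arrays and 1.309, 1.466 and 1.477 in the well-watered ones. The late-day arrays did not overlap either, with 1.508, 1.747 and 1.504 against 1.456, 1.378 and 1.262, a difference of 0.221 against 0.189 at pre-dawn. With these differences for 3 control genes as covariates 15 probe sets passed at pre-dawn, with AT5MAT as the only one of the named genes above.

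**Figure D2:**
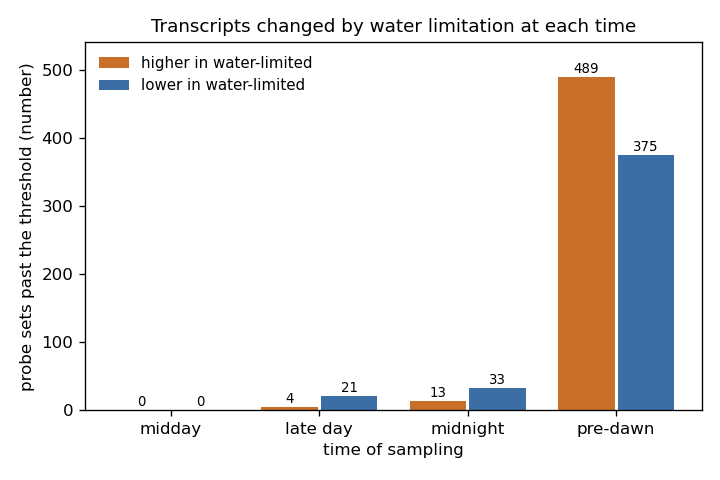
Number of probe sets with an adjusted p under 0.05 (vertical axis) for water-limited against well-watered plants at each time of day, split into higher and lower in water-limited plants. Midday had 0, late day 25, midnight 46 and pre-dawn 864.

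Of the genes named for midnight, AT1G47400 had the largest fall and ASPGB1 the largest rise. AT1G47400, which encodes a small peptide induced by iron deficiency, fell from 7.88 ± 0.33 to 4.95 ± 0.78 log2, a change of −2.92 (SE 0.33, 7.59-fold lower, adjusted p = 0.000111). ASPGB1 (AT3G16150), an asparaginase, rose from 4.89 ± 0.55 to 6.53 ± 0.22, a change of 1.65 (SE 0.25, 3.13-fold, adjusted p = 0.00278). AT5G05250 fell from 7.04 ± 0.1 to 5.72 ± 0.18, a change of −1.32 (SE 0.19, adjusted p = 0.00127). The copper amine oxidase gene AT3G43670 rose by 1.43 log2 (SE 0.25, adjusted p = 0.0102), and by 1.16 at pre-dawn (adjusted p = 0.0102). AT3G23170 rose by 1.11 (adjusted p = 0.0271) and AT1G10690 by 0.74 (adjusted p = 0.0168). The MYB-related gene AT4G37180 changed by −1.87 log2 (adjusted p = 0.0331), AT1G75960 by −1.86 (adjusted p = 0.0238) and the pectin methylesterase gene ATPMEPCRB (AT4G02330) by −1.28 (adjusted p = 0.0456). AT3G15450 changed by −1.17 (adjusted p = 0.0459) and AT1G09390 by −1.12 (adjusted p = 0.0485). The 3 flavonoid and anthocyanin genes had a median change of 1.36; 0 of 3 were past the threshold of limma over all probe sets and 2 were adjusted over the list alone (camera adjusted p = 0.00323; adjusted p = 0.204 with an estimated correlation). No gene of the photosynthesis list or of the expansins and xyloglucan hydrolases passed limma at midnight, with 1 and 0 adjusted over the list alone and camera adjusted p of 0.841 and 0.598.

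In total 46 probe sets differed at midnight, 13 higher and 33 lower, and 33 of them by at least 2-fold, with 1591 at an unadjusted p under 0.05. The balance of directions depended on scaling, with 24 higher and 24 lower after median centring and 24 higher and 29 lower after quantile normalization. In 1843 probe sets (15.5%) the arrays did not overlap. The count was 16 without well-watered midnight replicate 1 or 2, 113 without well-watered midnight replicate 3, 20 without water-limited midnight replicate 1 and 111 without water-limited midnight replicate 2. It was 30 without well-watered midday replicate 3, 70 without water-limited midday replicate 1 or water-limited late-day replicate 2, and 100 without water-limited pre-dawn replicate 2. AT1G47400, ASPGB1 and AT5G05250 stayed past the threshold without any one array, and the other genes named for midnight were not past it without 3 or more of the arrays, well-watered midnight replicates 1 and 2 and water-limited midnight replicate 1 among them.

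Of the genes named for late day, AT2G20670 had the largest change. It fell from 8.46 ± 0.65 to 5.22 ± 0.4 log2, a change of −3.24 (SE 0.5, 9.46-fold lower, adjusted p = 0.00361). Its change at midnight was −2.22 (adjusted p = 0.0529). AT5G53420, which encodes a CCT-motif protein, rose from 6.77 ± 0.26 to 8.32 ± 0.15, a change of 1.54 (SE 0.3, 2.91-fold, adjusted p = 0.0307), and by 1.22 at pre-dawn (adjusted p = 0.0187). AT3G44610 rose by 0.94 log2 (adjusted p = 0.0472). AT1G53430 changed by −1.09 (adjusted p = 0.0324), AT4G29950 by −1.02 (adjusted p = 0.0318) and AT4G05070 by −0.87 (adjusted p = 0.0307). No tested member of the 4 lists fixed in advance with at least 3 tested genes passed limma at late day; the median change was 0.33 for flavonoid and anthocyanin genes, −0.09 for photosynthesis genes and −0.03 for expansins and xyloglucan hydrolases (camera adjusted p 0.567, 0.567 and 0.798), with 1 photosynthesis gene higher adjusted over the list alone.

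In total 25 probe sets differed at late day, 4 higher and 21 lower, and 22 of them by at least 2-fold, with 1085 at an unadjusted p under 0.05. Their p came from a spread shared by all groups. The mean variance between replicates was 0.1773 in water-limited late-day plants and 0.0728 to 0.1079 in the other groups. The errors and p for late day, alone or against another time, may therefore be too small and the calls too many. With the late-day arrays fitted alone, and a spread estimated from fewer arrays, no probe set passed. In 1606 probe sets (13.5%) the arrays did not overlap. The count was 11 without well-watered late-day replicate 1 or water-limited late-day replicate 3, and 13 without well-watered late-day replicate 2. Of 10 splits of the late-day arrays, 2 gave as many calls, the real one included, and the other gave 212. Chance was therefore not excluded for this count. AT2G20670 stayed past the threshold without any one array, and the other genes named for late day were not past it without 5 or more of the arrays, well-watered late-day replicates 1, 2 and 3 among them. With the 3 control differences as covariates 11 probe sets passed at late day, of which 8 were among the 25.

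At midday no gene passed the threshold of limma: 0 probe sets differed between the regimes, with 593 at an unadjusted p under 0.05 where 596 would be expected by chance. The arrays did not overlap in 1416 probe sets (11.9%). At midday the change of AT1G47400 was −0.06 log2, that of AT5MAT 0.30, that of DFR 0.5 and that of AT2G20670 −0.78. The median change was 0.72 for the flavonoid and anthocyanin genes, 0.06 for the photosynthesis genes and −0.1 for expansins and xyloglucan hydrolases (camera adjusted p 0.138, 0.475 and 0.194), with 1 photosynthesis gene higher adjusted over the list alone. The simulated 2-fold changes were found at midday in 68.7% of cases, with 200 changed probe sets and the same simulated spread at all times. The count was 11 without the filter, 2 without well-watered midday replicate 2 or well-watered pre-dawn replicate 3, and 1 without water-limited midday replicate 2, water-limited late-day replicate 3 or well-watered pre-dawn replicate 2.

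The average of the drought effects over the 4 times asked which transcripts changed in the mean of the times, which a change at some of the times can bring about. DFR was called on average with a change of −0.08 at late day and 2.97 at pre-dawn. The glutaredoxin gene AT3G62960 rose by 1.90 log2 (SE 0.3, 3.74-fold, adjusted p = 0.00077, n = 12 arrays of each regime) and AT4G33040 by 1.58 (SE 0.24, 2.99-fold, adjusted p = 0.000555). SWEET13 rose by 1.57 (SE 0.31, adjusted p = 0.00359), UF3GT by 1.56 (SE 0.25, adjusted p = 0.000769) and AT1G80130 by 1.52 (SE 0.28, adjusted p = 0.00199). AT1G49500 changed by −1.69 (SE 0.27, 3.23-fold lower, adjusted p = 0.000769), AT2G20670 by −1.64 (SE 0.25, adjusted p = 0.000555) and AT5G19120 by −1.39 (SE 0.27, adjusted p = 0.00316). The size for AT2G20670 is a lower bound, since 1 of its water-limited pre-dawn arrays lay at the floor. The lectin-like gene AT5G03350 changed by −1.36 (SE 0.4, adjusted p = 0.0347) and the putative chitinase gene CHI (AT2G43570) by −1.30 (SE 0.32, adjusted p = 0.0138). Each of these 10 genes had the same sign at all 4 times, except AT5G03350, whose change at late day was 0.03. All 3 flavonoid and anthocyanin genes rose, and so necessarily also when adjusted over the list alone (median 1.32, camera adjusted p = 0.000348, and adjusted p = 0.1 with an estimated correlation). LHCB4.3 rose by 0.55 (SE 0.08, adjusted p = 0.000522) and EXPA8 fell by 0.52 (SE 0.15, adjusted p = 0.0331), in lists with camera adjusted p of 0.553 each, and 0 of the 4 ABA- and dehydration-responsive genes passed limma (median −0.11, camera adjusted p = 0.831).

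In total 1205 probe sets (10.1%) differed on average, 663 higher and 542 lower, and 81 of them by at least 2-fold, with 3114 at an unadjusted p under 0.05. The count was 786 without well-watered midnight replicate 1, 752 without water-limited pre-dawn replicate 1 and 735 without water-limited pre-dawn replicate 3. With the 3 control differences as covariates it was 312, and AT5G03350, EXPA8 and AT4G14090 were no longer past the threshold, with changes of −1.34 (adjusted p = 0.162), −0.35 (adjusted p = 0.258) and 1.02 (adjusted p = 0.13). AT5G03350 was also not past it without any one of well-watered midday 1 or 2, water-limited midday 3, well-watered late day 2 or 3, water-limited late day 3, well-watered midnight 1, water-limited midnight 1, well-watered pre-dawn 1 or 3, or water-limited pre-dawn 1 or 3, with an adjusted p of at most 0.0746. EXPA8 was not past it without any one of well-watered midday 1 or 2, water-limited midday 2, well-watered late day 1 or 2, water-limited late day 2, well-watered midnight 2, water-limited midnight 1, well-watered pre-dawn 1 or 3, or water-limited pre-dawn 1 or 3, with an adjusted p of at most 0.0718.

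The other fixed lists had few named genes on the array. In 11 of them 1 or 2 members were tested, 19 genes in all, and limma called 0 of the 19 at any single time. They were STZ of the CBF/DREB and ZAT factors; GI and AT5G52660 of the clock; PWD and DPE1 of starch turnover; the Aux/IAA genes IAA18 and IAA29; PDF1.2 and THI2.1 of jasmonate; WRKY53 and GRX480 of salicylate and defence; BCAT4 and AT2G31790 of glucosinolates. The rest were PRL and AUR1 of cell division, WRKY6 of senescence, FMA and AT1G22690 of guard cells and PYK10 of roots. Adjusted over the list alone, 0 were called at midday, 1 higher and 1 lower at late day, 1 higher and 1 lower at midnight, and 3 higher at pre-dawn. For the average over the times 1 was higher and 2 lower adjusted over the list alone, and the clock gene AT5G52660 rose by 0.37 log2 over all probe sets (adjusted p = 0.0307). It was not past the threshold with the control covariates or without the filter, nor without any one of well-watered midday 3, water-limited midday 1, water-limited late day 1, water-limited midnight 1, or well-watered or water-limited pre-dawn 3, with an adjusted p of at most 0.0616. The guard cell gene FMA changed by 0.79 at pre-dawn (adjusted p = 0.0532) and the root gene PYK10 by −1.99 at late day (adjusted p = 0.193). No member was tested for ABA receptors, clade A protein phosphatases 2C, ABA synthesis and breakdown, proline and raffinose-family metabolism, sugar starvation, aquaporins, heat shock, or flowering and bolting.

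The overlap between times showed whether transcripts changed at one time were also changed at another. Of the genes that fell at midnight, AT1G47400, AT5G05250, AT3G47800 and AT3G15450 fell at pre-dawn too, with changes of −1.38 (adjusted p = 0.0164), −0.67 (adjusted p = 0.0344), −1.58 (adjusted p = 0.00378) and −0.84 (adjusted p = 0.049). Midnight and pre-dawn shared 10 probe sets that were higher, where 0.533 were expected, and 19 that were lower, where 1.04 were expected. Late day and midnight shared 4 that were lower (0.0581 expected), and late day and pre-dawn shared 1 higher (0.164 expected) and 2 lower (0.66 expected). The expected counts treat the calls at 2 times as independent. All times used the same estimate of the spread of a probe set, which can raise the shared counts above them. Across probe sets, which are not independent replicates, the changes at midnight and pre-dawn had a correlation of 0.579, those at late day and midnight 0.469, and those at late day and pre-dawn 0.291. With midday the correlations were 0.19 for late day, 0.252 for midnight and 0.232 for pre-dawn. The 489 probe sets higher at pre-dawn had median changes of 0.14 at midday, 0.16 at late day and 0.37 at midnight, and 87.1% of them were above 0 at midnight. Of the 375 lower at pre-dawn, 92.8% were below 0 at midnight.

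**Figure D3:**
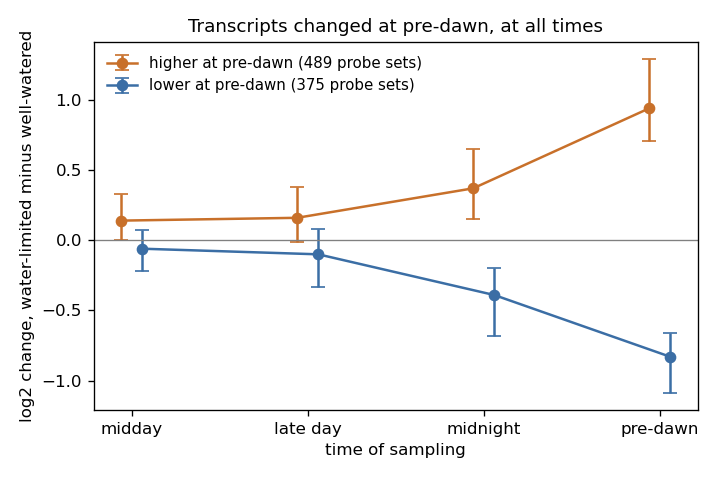
Change (log2, water-limited minus well-watered) at each time of day of the probe sets that differed at pre-dawn, with the median and quartiles of the 489 higher and of the 375 lower ones. The medians of the higher set were 0.14 at midday, 0.16 at late day, 0.37 at midnight and 0.94 at pre-dawn.

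The shared count of 29 between midnight and pre-dawn was 19 without well-watered midday replicate 1 or 2, 18 without well-watered midday replicate 3, 10 without well-watered midnight replicate 1, 11 without well-watered midnight replicate 2, 64 without well-watered midnight replicate 3, 12 without water-limited midnight replicate 1, and 51 without water-limited midnight replicate 2. It was 12 without well-watered pre-dawn replicate 1 or 3, 7 without water-limited pre-dawn replicate 1, 72 without water-limited pre-dawn replicate 2 and 10 without water-limited pre-dawn replicate 3.

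AT2G20670 and AT5MAT are 2 examples of how transcripts with a drought effect varied over the day. AT2G20670 differed between times in well-watered plants (adjusted p = 1.73e-08), with a range of 5.92 log2. Its mean in water-limited plants at pre-dawn was 2.2 ± 0.01, next to the lowest value in the table. Its range of at least 3.02 log2 in water-limited plants is therefore a lower bound. So is the size of its drought effect at pre-dawn and on average. AT5MAT had a range of 0.49 in well-watered plants (adjusted p = 0.769) and 3.63 in water-limited plants (adjusted p = 5.9e-06). The water-limited pre-dawn arrays for which AT5MAT was named also set the wider range, so the 2 ranges are no separate evidence. Its drought effect was not shown to differ between the 4 times (adjusted p = 0.0648 by the moderated F-test).

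The question in the study's title is whether the drought effect itself depends on the time of day, which the test of a difference between times addresses. AT1G47400 had changes of −0.06 at midday, −0.05 at late day, −2.92 at midnight and −1.38 at pre-dawn, and these differed (adjusted p = 0.0332, SE of each change 0.33). The change at midnight minus that at late day was −2.88 log2 (adjusted p = 0.0221), and minus that at midday it was −2.87 (adjusted p = 0.0567). AT5G05250 had changes of 0.16, 0.47, −1.32 and −0.67 at the same times (adjusted p = 0.0332, SE 0.19). AT5G05140 had changes of 0.97, −0.51, −0.07 and 0.17 (adjusted p = 0.0393, SE 0.16). The next of the 10 genes with the smallest p was AT5MAT, which did not pass this test over the 4 times (adjusted p = 0.0648), followed by AT3G61820, AT3G50280 and AT3G06780 (adjusted p = 0.0826 each), AT3G17770 (adjusted p = 0.0924), and AT5G65380 and AT1G33590 (adjusted p = 0.0967 each). For pre-dawn minus late day alone, limma called AT5MAT (3.53 log2, adjusted p = 0.0282), AT3G61820 (−0.97, adjusted p = 0.0282), AT3G06780 (1.61, adjusted p = 0.0282) and AT1G33590 (−1.15, adjusted p = 0.0299). AT3G50280, AT3G17770 and AT5G65380 were not past the threshold for that pair. The drought effect on AT3G50280 was 1.06 at pre-dawn and −0.59 at midday, and that on AT5G65380 was 1.07 and −0.02. The mean drought effect on the 3 flavonoid and anthocyanin genes was 2.35 log2 larger at pre-dawn than at midday (camera adjusted p = 0.000722; adjusted p = 0.126 with an estimated correlation). The mean effect on the 4 ABA- and dehydration-responsive genes was 0.76 log2 larger at midnight than at midday (camera adjusted p = 0.0222; adjusted p = 0.257 with an estimated correlation) and 0.64 larger than at late day (camera adjusted p = 0.0234; adjusted p = 0.285 with an estimated correlation). For the flavonoid and anthocyanin genes it was 1.07 larger at midnight than at late day (camera adjusted p = 0.0234; adjusted p = 0.285 with an estimated correlation). At pre-dawn it was 2.71 larger than at late day (camera adjusted p = 0.000207; adjusted p = 0.0859 with an estimated correlation) and 1.64 larger than at midnight (camera adjusted p = 0.0112; adjusted p = 0.156 with an estimated correlation). For expansins and xyloglucan hydrolases the effect at pre-dawn minus that at midnight was −0.48 (camera adjusted p = 0.013; adjusted p = 0.054 with an estimated correlation).

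**Figure D4:**
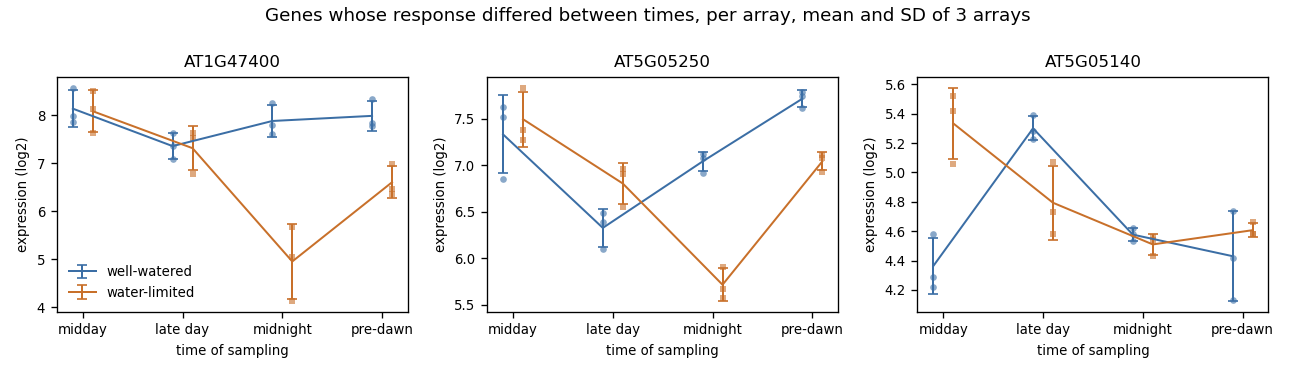
Expression (log2) at the 4 times of day of the named genes whose drought effect differed between times, in well-watered and water-limited plants, with points for single arrays and bars for the mean and SD of 3 arrays. AT1G47400 at midnight had a mean of 7.88 in well-watered and 4.95 in water-limited plants.

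In total the drought effect differed between times in 6 probe sets, 3 of them with a named gene, and 1213 had an unadjusted p under 0.05 against 596 by chance. The count was 1193 with array quality weights, 37 without the filter, 11 with trend and robust moderation, and 3 with quantile normalization or with probe sets of exactly 1 gene. Between pairs of times, 25 probe sets differed between pre-dawn and late day, 6 between midnight and late day and 1 between late day and midday, with 1545, 500 and 594 at an unadjusted p under 0.05. By limma 0 differed between pre-dawn and midday (1589 at an unadjusted p under 0.05), 0 between midnight and midday (834) and 0 between pre-dawn and midnight (709), so no single probe set was shown to differ in its drought effect between pre-dawn and midday. The count of 6 was 0 without any one of water-limited midday 3, well-watered late day 1 or 2, well-watered midnight 2 or 3, water-limited midnight 2, well-watered pre-dawn 1, or water-limited pre-dawn 1 or 3. It was 2 without well-watered midday 1 or water-limited late day 1, 3 without well-watered late day 3, 10 without water-limited midday 1, 16 without water-limited late day 2 and 211 without water-limited pre-dawn 2.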

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

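The comparisons of replicate spread between single times were chosen after the result had been seen. The fit with control covariates was chosen after the counts and the control values had been seen and before that fit was made.

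The drought effect differed between the 4 times in 6 probe sets by the test of the difference itself. The named genes among them were AT5G05250 (adjusted p = 0.0332), AT1G47400 (adjusted p = 0.0332) and AT5G05140 (adjusted p = 0.0393), all by limma. Between pairs of times, 25 probe sets differed between pre-dawn and late day, 6 between midnight and late day and 1 between late day and midday. Chance was not excluded for the count of 6, since 5 of 100 splits of the arrays within each time gave at least as many and the highest of the other splits gave 113. The adjusted p over single omissions of arrays and other settings lay between 0.00182 and 0.185 for AT5G05250, between 0.000681 and 0.171 for AT1G47400, and between 0.00398 and 0.189 for AT5G05140. No biological explanation was tested for these 6 probe sets.

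More probe sets were called at pre-dawn than at the other times, 864 against 46 at midnight, 25 at late day and 0 at midday. In the fit all groups shared 1 estimate of the spread, so a smaller spread at pre-dawn would not lower the error used there. Replicate noise was also not smallest at pre-dawn, with 0.0518 against 0.0498 at midday, 0.0651 at midnight and 0.0866 at late day. The changes themselves varied more at pre-dawn than at midday and late day. Their variance left after each time's own replicate noise was at least 0.0925 at pre-dawn with any 1 array left out. It was at most 0.0499 at midday and late day. The contrast with midnight stays open. There that variance was 0.16 at pre-dawn and 0.0598 at midnight but reached 0.102 at midnight without well-watered replicate 3. RNA quality stays open as well. With the 3 control differences as covariates, 15 probe sets passed at pre-dawn and 127 at midnight. All 864 kept their direction. The median size of their change went from 0.89 to 0.75 log2, with 0.848 of it left, and the median SE went from 0.22 to 0.26. The 864 were chosen by the fit without covariates on the same arrays. Their kept direction and size therefore do not count against RNA quality. Both the smaller change and the larger error lower the number of calls, and the covariates also take up residual degrees of freedom. A drought response that may be stronger before dawn cannot be told apart from a part played by RNA quality. The labels give 4 days without water for every water-limited group. A difference between the times in hours without water therefore cannot be told apart from the time of day.

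The condition on the share of the change left was added after that share had been seen. An earlier test, whether the control differences between regimes were largest at pre-dawn, held for 1 of the 3 control genes and was replaced by the fit with covariates.

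The poly-A control transcripts, which are not part of the comparisons, had a mean of 11.092 log2 in water-limited midnight replicate 3, above the range of 5.115 to 7.935 in the other 23 arrays.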

How the results depend on the processing

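The fits with covariates, the fit without the 6 late-day arrays and the gene-by-gene array weights were chosen after the data had been seen. No call of a named gene and no list call reversed its direction under the settings run, while 7 list medians within 0.05 log2 of 0 changed sign with scaling, that of the photosynthesis genes at midnight going from −0.01 to 0.02 with median centring and −0.05 with quantile normalization. The cause of a change in a count was not tested unless stated. Low signal limits what can be seen, since 25.5% of values lay at the floor.

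With 1 array left out in turn, the calls ranged from 0 to 2 at midday, 11 to 33 at late day, 16 to 113 at midnight, 91 to 1793 at pre-dawn, 735 to 1698 for the average effect and 0 to 211 for the difference between times. The calls shared by midnight and pre-dawn ranged from 7 to 72 around 29. Where a group keeps 2 arrays, they are assumed to vary like the other groups. The time-of-day counts ranged from 5004 to 6566 in well-watered and from 5525 to 6919 in water-limited plants.

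Without the filter there were 11 calls at midday, 547 at pre-dawn, 763 for the average and 37 for the difference, with 15 shared. With the stricter filter there were 11 at late day and 29 at midnight, from fewer probe sets. With array weights there were 3 at midday, 52 at late day, 70 at midnight, 4252 at pre-dawn, 2160 for the average and 1193 for the difference, with 58 shared. With trend and robust moderation there were 11 for the difference and 44 shared, and with quantile normalization 3 for the difference.

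Replicate numbers did not pair the arrays of the 2 regimes: 12 correlations between arrays of equal number ran from −0.538 to 0.093. With a block for each pair of equal number at a time there were 13 calls at late day, 8 at midnight and 199 at pre-dawn. There were 484 for the average and 0 for the difference, with 3 shared. That fit leaves fewer residual degrees of freedom. Probe sets with exactly 1 gene, which are fewer, gave 1 call at midday, 1 at late day, 13 at midnight, 401 at pre-dawn, 552 for the average and 3 for the difference, with 7 shared, and 3015 and 3216 for time of day in well-watered and water-limited plants. The 6 arrays of 1 time alone, with a spread estimated from fewer arrays, gave 0 calls at late day, 0 at midnight and 7 at pre-dawn.

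With the 3 control differences as covariates there were 11 calls at late day, 127 at midnight, 15 at pre-dawn and 312 for the average, with 1 shared. At pre-dawn the GAPDH difference alone left 376 and the ubiquitin difference alone 499. The camera calls for drought effects at single times and on average were 3 for the lists fixed in advance and 12 for the lists added later. With an estimated correlation in camera, 0 of the 3 and 0 of the 12 passed. All 15 passed with median centring, with the block and with the mean over the probe sets of a locus. The camera calls for differences between times are not among these 15.

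For the 121 pairs of a named gene and an effect, quantile normalization left 115 and median centring 116 on the same side of the threshold, moderation with trend 116, array weights 113, no filter 76, probe sets with 1 gene 109, the block 57 and the covariates 49. The stricter filter kept 90 of 90, the fit without the late-day arrays 40 of 50, and the arrays of 1 time alone 0 of 56. With 1 array left out, 2450 of 2904 were on the same side, 440 were no longer past the threshold and 14 had come past it. The unmoderated F-test left 7 of 10 on the same side.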

Other observations

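The tests of array quality for the late-day arrays and the plastid-encoded list's values without single arrays were chosen after their scatter had been seen, as were the 17 further gene lists after the annotation had been read.

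Of the 8 tested genes of tetrapyrrole synthesis, the pathway of chlorophyll and haem, 4 fell at pre-dawn under water limitation. PORB (AT4G27440) changed by −0.92 log2 (SE 0.22, adjusted p = 0.0162), CHLI2 (AT5G45930) by −0.84 (SE 0.25, adjusted p = 0.0477), HEME1 (AT3G14930) by −0.81 (SE 0.22, adjusted p = 0.034) and CHLM (AT4G25080) by −0.52 (SE 0.16, adjusted p = 0.045), all by limma. The other 4 were not past the threshold and 1 of the 8 was above 0. The median change was −0.69, and the list ranked below other probe sets (camera adjusted p = 0.000141; adjusted p = 0.504 with an estimated correlation). It did so too at late day (median −0.27, camera adjusted p = 0.0115; adjusted p = 0.73 with an estimated correlation), at midnight (−0.44, camera adjusted p = 0.000855; adjusted p = 0.554 with an estimated correlation) and on average (−0.31, camera adjusted p = 3.67e-05; adjusted p = 0.546 with an estimated correlation). For the 44 plastid-encoded photosynthesis genes, 0 passed limma, and the mean change was −1.03 at late day (camera adjusted p = 3.31e-14; adjusted p = 0.73 with an estimated correlation). At pre-dawn the median change was −0.52 (camera adjusted p = 0.00114; adjusted p = 0.567 with an estimated correlation) and on average −0.49 (camera adjusted p = 1.76e-05; adjusted p = 0.638 with an estimated correlation). At midday and midnight the medians were −0.02 and −0.04 (camera adjusted p = 0.54 and 0.963). The late-day and average values rested on water-limited late-day replicate 2. The mean of the 44 genes was 9.06 log2 in that array, 11.39 and 10.79 in water-limited replicates 1 and 3, and 11.80, 11.32 and 11.21 in the well-watered arrays. Without replicate 2 the mean change was −0.35 at late day, with a median of −0.20, and −0.28 on average against −0.45 with all arrays. Without any one of the other late-day arrays, the mean change at late day lay between −1.52 and −0.85.

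Of the 10 tested autophagy genes ATG8 and ATG3, 2 rose at pre-dawn and 0 passed limma at midnight. APG8H (AT3G15580) rose at pre-dawn by 0.84 log2 (SE 0.19, adjusted p = 0.0133) and ATG3 (AT5G61500) by 0.5 (SE 0.14, adjusted p = 0.0364). In this list 9 were above 0 at pre-dawn, with a median of 0.51 (camera adjusted p = 0.000814; adjusted p = 0.504 with an estimated correlation). The median was 0.32 at midnight (camera adjusted p = 0.0372; adjusted p = 0.719 with an estimated correlation) and 0.31 on average (camera adjusted p = 0.000816; adjusted p = 0.546 with an estimated correlation). Among 6 SWEET sugar transporters, SWEET13, SWEET4 (0.96, adjusted p = 0.0361) and SWEET1 (0.67, adjusted p = 0.0394) rose at pre-dawn. Among 21 UDP-glycosyltransferases, UGT84A3 (1.46, adjusted p = 0.00942) and UGT78D2 rose, and UGT76C2 and UGT88A1 (−0.53, adjusted p = 0.0466) fell; the list's median at midnight was 0.15 (camera adjusted p = 0.0372; adjusted p = 0.719 with an estimated correlation). Of 12 trichome birefringence-like genes, TBL26 (1.49, adjusted p = 0.0128) and TBL38 (1.38, adjusted p = 0.0119) rose at pre-dawn, and the xyloglucan enzyme gene EXGT-A3 fell (−0.86, adjusted p = 0.0128).

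Of 5 tested iron-deficiency genes, 1 was called at pre-dawn and 2 on average, and the list did not stand out from other probe sets (camera adjusted p = 0.818 and 0.923). ILR3 rose at pre-dawn (0.48, adjusted p = 0.0219) and on average (0.23, adjusted p = 0.0186), and PYE, a regulator of the iron-deficiency response, fell on average (−0.47, adjusted p = 0.0186) with a change of −1.10 at midnight (adjusted p = 0.0514). The auxin-conjugating gene WES1 rose at pre-dawn (1.12, adjusted p = 0.0288), the histone gene HTB2 fell (−0.92, adjusted p = 0.0338), and the tubulin gene TUB5 fell (−0.52, adjusted p = 0.0349). The co-chaperone gene ATERDJ2B fell at midnight (−1.06, adjusted p = 0.0168), where the 10 chaperone and co-chaperone genes had a median of −0.22 (camera adjusted p = 0.0386; adjusted p = 0.554 with an estimated correlation). By limma 0 of 9 LEA protein genes, 0 of 6 glutathione transferases, 0 of 4 U-box ligases, 0 of 2 calmodulin-like genes and 0 of 2 stomatal lineage genes passed at any single time. On average the LEA protein gene AT2G46140 (0.38, adjusted p = 0.0252) and GSTU16 (0.5, adjusted p = 0.0404) rose and GSTU18 (−0.3, adjusted p = 0.0328) fell, and none of the 3 passed with the control covariates or without the filter; leaving out single arrays ended the call in 2 of 24 cases for AT2G46140, 13 for GSTU16 and 11 for GSTU18. Of the pre-dawn calls in these lists, the genes other than UGT78D2 and UGT76C2 were not past the threshold without water-limited pre-dawn replicate 1 or without replicate 3. With the 3 control differences as covariates, none of the pre-dawn calls in these lists passed, nor did the average calls of ILR3 and PYE, while ATERDJ2B at midnight did.

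Other splits of the arrays were fitted for each comparison. For a single time, 10 splits into 3 and 3 are too few to give a share under 0.05. At midday the real count was 0 and the highest other 0, with 10 of 10 as large. At late day they were 25 and 212, with 2 of 10 as large, at midnight 46 and 0, with 1 of 10, and at pre-dawn 864 and 67, with 1 of 10. For the average effect chance was excluded, with 1205 calls against at most 59 in 99 other splits. The same holds for time of day, with 5954 against at most 2459 in well-watered and 6389 against at most 2478 in water-limited plants, where only 1 of 100 splits was as large.

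The 3 water-limited late-day arrays scattered more than other groups, with a median SD of 0.273 log2 against 0.165 to 0.243. The split that called 212 probe sets set water-limited replicates 1 and 2 and well-watered replicate 1 against the others. What lies behind this split was not tested. For the scatter, array or RNA quality may play a part and stays open. Water-limited replicate 2 lay outside the range of the other arrays in 3 of 6 control measures. Water-limited midnight replicate 3 did so in 4, but with a mean correlation of 0.9904 within its group, against 0.9815. Plants at different phases of the day and at different stages of water limitation also stay open. The main axis of the scatter correlated with the well-watered difference between midnight and midday at 0.082 and with the drought effect of the other times at 0.09 across probe sets, under the bound of 0.1 set beforehand, but with 1 array left out these values reached 0.106 and 0.144.

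A phase shift was weighed as a source of the drought effects, which would then resemble the well-watered change from the previous to the next time. The correlations across probe sets were −0.089 at midday, −0.015 at late day, 0.084 at midnight and 0.126 at pre-dawn, and the largest in the other splits were 0.139, 0.135, 0.103 and 0.149. At 0 of the 4 times did the real value exceed all 9 other splits, and the sign was not the same at all times. These values gave no sign of a common shift. They cannot exclude one, because no shift was simulated and 10 splits are too few to give a share under 0.05. A shift that differs between genes was not tested.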
